A study of Mus musculus with 14 samples.

How the data were processed

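The study measured gene expression by RNA sequencing in LT-HSCs and GMPs sorted from the bone marrow of C57BL/6 mice, per the labels' protocols. Poly(I:C) is listed at 5 mg/kg in 4 doses for all 14 samples, controls included. In AML1-ETO mice it activated Mx1-Cre, a recombinase driven by an interferon-responsive promoter, and so switched on Runx1-Runx1t1. RNA was extracted with a micro-column kit, and libraries were prepared with a SMART-Seq low-input kit and a SMARTer stranded kit, both named per the labels without saying which step or library each served. The labels do not give the sort markers, the sex of the mice or the sequencing batches. HISAT2 2.0.5, featureCounts 1.5.0-p3 and the mm10 build are named per the submitters' processing notes, with no roles. The strand setting and the annotation release are not given in the sources used here, so reads of a gene and of an overlapping or antisense gene cannot be told apart, and near-identical genes such as globins, immunoglobulin segments, mast cell proteases and Xlr3 copies share or lose reads in an unknown way.

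The authors deposited 1 table of raw counts per gene, whole numbers that are not normalised, for 54532 gene symbols in 14 columns, whose names match the sample titles. The column totals run from 13210952 to 19403864 counts. There is no line without a symbol, 105 lines repeat an earlier symbol, and 27 lines carry a date in place of a symbol, as spreadsheet software makes of names such as those of the Septin and March families. Those 27 lines hold 0.140% of the counts, stayed in the tests (17 to 20 of them passed the filters) and are not named. The table gives no biotype, so the rule for named genes was applied without one. Gene coordinates were taken by symbol from GENCODE M21, an annotation of mm10, which knew 98.9% of the symbols. Replicates of a group differed by far more than counting noise, with a chi-square per gene of 9.20 to 216, so no library appears to have been deposited a second time.

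Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Genes were filtered with edgeR's filterByExpr on the groups, scaled by TMM and tested with edgeR's quasi-likelihood F test (glmQLFit and glmQLFTest), two-sided, with Benjamini-Hochberg adjustment over all genes tested. A gene was called at an adjusted p under 0.05. AML1-ETO was compared with control within each cell type on its 7 samples, which leaves 5 residual degrees of freedom. The difference between the cell types and the comparison of GMPs with LT-HSCs within each genotype used 1 fit of all 14 samples and 4 groups, with 10 residual degrees of freedom. The common biological coefficient of variation was 0.785 in LT-HSCs, 0.460 in GMPs and 0.728 over all samples. CPM levels were computed from TMM-scaled library sizes. A gene with 0 counts in every library of a group was compared with a floor of 3 counts over the group, 0.0490 CPM in control and 0.0702 CPM in AML1-ETO LT-HSCs and 0.0413 CPM in control and 0.0623 CPM in AML1-ETO GMPs in the comparisons within a cell type, and its fold is given as at least that size. A fitted fold change of such a gene has no SE here. Floors cover counting error only, since the reads carry no molecular identifiers. Genes with 1 to 3 counts in a group are given as levels only.

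The comparisons, their tests, the gene lists and a first set of alternatives were fixed before the data were examined, and what was added afterwards is named as such. The 25 lists hold 805 distinct genes of fatty acid synthesis, oxidation and uptake, triglycerides, eicosanoids, cholesterol, glycolysis, oxidative phosphorylation, the cell cycle, LT-HSC and GMP identity, 8 other blood, immune and stromal cell types, the interferon and immediate early responses, t(8;21) leukaemia, transcription factors, ribosomal proteins and sex-linked genes. Lists were chosen from general knowledge and overlap in part. Each list was tested against all other genes with camera (edgeR counts, preset correlation 0.01, two-sided), adjusted over the 25 lists of a comparison, and again with an estimated correlation. The lists that held with an estimated correlation were mast cell and cholesterol synthesis in LT-HSCs, mast cell, interferon and immediate early in GMPs, fatty acid synthesis, cholesterol, cell cycle, erythroid and mast cell for the difference, GMP identity and mast cell in control mice, and GMP identity, cell cycle, glycolysis and cholesterol in AML1-ETO mice. For the 4 fatty acid lists, the mean log2 CPM (prior count 2) of each sample was compared by a two-sided exact permutation test of 35 arrangements, whose smallest p is 0.0286, adjusted over 8 tests. Shares of counts per library were compared in the same way.

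Named genes followed a fixed rule. These were Runx1 and Runx1t1, the 8 largest rises and 8 largest falls among called genes with a mean of at least 20 counts and no overlap between the groups, and up to 4 members of each list with the smallest p. For the difference between cell types, up to 5 genes per direction with the smallest p were named, and for GMPs against LT-HSCs up to 6 members of both identity lists and the 5 largest changes per direction. Genes named outside this rule are said to have been chosen after their values were seen, and the members that make up a count of 5 or fewer were named in the same way. Results of some genes are not reported here, so a few counts have fewer names than members.

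The test was checked on simulated counts with the library sizes and control means of the real samples and 1 spread per gene for every group. In them, 67, 67 and 66 genes were changed 2-fold, 4-fold and 8-fold. For GMPs against LT-HSCs, the control LT-HSC means stood for both cell types. Real replicates were not equally alike, with mean correlations of 0.985 in control and 0.859 in AML1-ETO GMPs and of 0.821 and 0.943 in LT-HSCs. The shares below may therefore not hold for the real samples. For AML1-ETO against control in LT-HSCs (13163 genes), edgeR recovered 4.5% of genes changed 2-fold, 47.8% of those changed 4-fold and 54.5% of those changed 8-fold, and 1.3% of its calls were unchanged genes. In GMPs (13315 genes) it recovered 37.3, 68.7 and 80.3%, with 5.0% unchanged genes among its calls. For the difference between cell types (15020 genes) it recovered 1.5, 35.8 and 54.5% with none, for control mice (14731 genes) 22.4, 53.7 and 72.7% with 2.9%, and for AML1-ETO mice (14737 genes) 13.4, 40.3 and 65.2% with none. With 4.5% recovered by edgeR, a change of 2-fold is mostly missed in LT-HSCs. Among the calls of DESeq2, 28.4 to 35.0% were unchanged genes, so DESeq2 counts are read with care.

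The alternatives set beforehand were DESeq2's Wald test, limma's voomWithQualityWeights, DESeq2 size factors and upper-quartile factors in edgeR, no filter on low counts, a filter of a mean of 50 counts, a log2 fold change over 1 as a further threshold, another set of samples in the fit, the replicate number as a block, leaving out each replicate in turn, and, for lists and scores, an estimated correlation, fry and a prior count of 0.5. Chosen after seeing the data were a filter of a mean of 10 CPM, the protein-coding genes of GENCODE M21, leaving out immunoglobulin genes, leaving out control LT-HSC replicates 2 and 3, and leaving out AML1-ETO GMP replicates 1 and 3 in the fit of all 14 samples. Other splits of the samples into groups of the same sizes were also fitted. No sample was left out of the comparisons, and no per-sample column was unused.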

Results

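RNA was sequenced from 14 bulk samples of mouse bone marrow sorted as LT-HSC, the long-term haematopoietic stem cells, or as GMP, the granulocyte-monocyte progenitors. The series title links the study to fatty acid metabolism and to a block of differentiation before leukaemia. AML1-ETO mice expressed Runx1-Runx1t1, the mouse form of the fusion made by the t(8;21) translocation of acute myeloid leukaemia, which joins the DNA-binding part of RUNX1 to most of RUNX1T1. Expression of the fusion was induced through Mx1-Cre by 4 intraperitoneal doses of poly(I:C) at 5 mg/kg. The labels list the same doses for all 14 samples, controls included. Each cell type had 3 AML1-ETO and 4 control libraries, and the libraries held 13210952 to 19403864 counts over 54532 genes. The labels do not say that the libraries came from separate mice, so p-values measure the spread between these samples, which may be technical. Levels below are in CPM, counts relative to the library total after TMM scaling, as mean ± SD with n = 3 for AML1-ETO and n = 4 for control, and log2 fold changes are given ± SE with adjusted p-values from edgeR. Coordinates are those of mm10. Members that complete a count of 5 or fewer in a gene list were named after their values were seen, where they stand outside the fixed rule for named genes.

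The parts of the fusion were examined first, as a check of the labels. Runx1t1 (chromosome 4, 13743436 to 13893649) stood at 94.4, 176 and 133 CPM in AML1-ETO LT-HSCs, against 4.12, 0, 18.1 and 11.3 CPM in control LT-HSCs. It stood at 25.3, 25.6 and 44.5 CPM in AML1-ETO GMPs, against 2.52, 2.23, 1.62 and 2.63 CPM in control GMPs. The rise in GMPs had a log2 fold change of 3.82 ± 0.32 (adjusted p = 0.00162). In LT-HSCs the log2 fold change was 4.00 ± 1.08 (adjusted p = 0.0468). This call was lost without any 1 of the 3 AML1-ETO LT-HSC libraries, without control LT-HSC replicate 1 and without control LT-HSC replicate 4, with an adjusted p of up to 0.176. In both cell types every AML1-ETO library lay above every control library.

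Runx1 (chromosome 16, 92601466 to 92826149), whose reads can come from the normal gene and from the fusion, stood at 317, 474 and 320 CPM in AML1-ETO LT-HSCs and at 196, 140, 134 and 169 CPM in control LT-HSCs. Its log2 fold change was 1.21 ± 0.22 (adjusted p = 0.0108), with an adjusted p of 0.0655 without AML1-ETO LT-HSC replicate 2. In GMPs Runx1 stood at 213, 213 and 164 CPM against 164, 204, 182 and 179 CPM, a log2 fold change of 0.11 ± 0.12 that did not pass the test (adjusted p = 0.660).

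**Figure D1:**
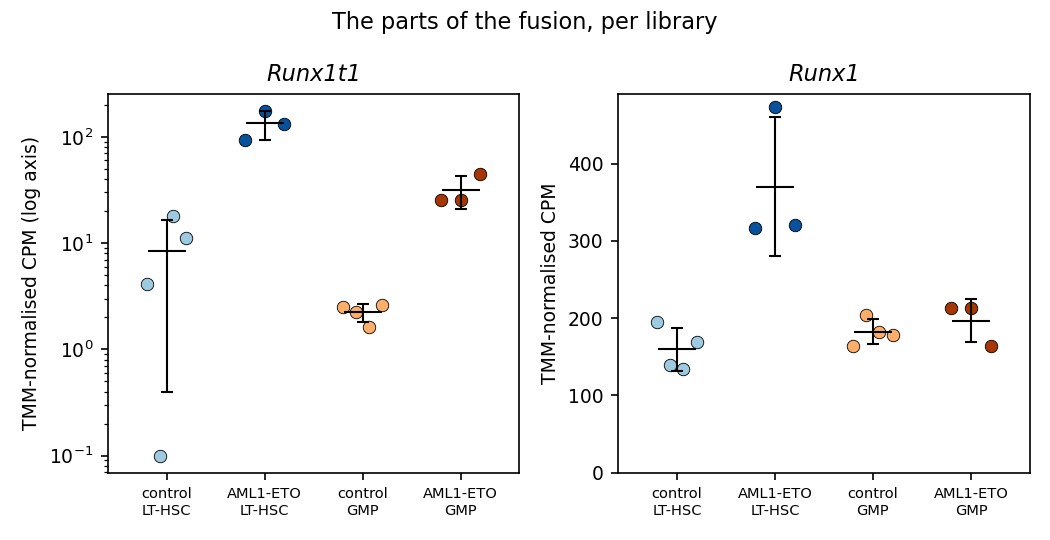
Runx1t1 (log axis, with a library without counts drawn at the lower end) and Runx1 (linear axis) in TMM-normalised CPM, 1 point per library, with bars for the mean ± SD of each of the 4 groups. In both cell types the 3 AML1-ETO libraries lie above the 4 control libraries for Runx1t1, with means of 134 against 8.37 CPM in LT-HSCs and 31.8 against 2.25 CPM in GMPs.

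The comparison of AML1-ETO with control LT-HSCs asks what the fusion changes in stem cells. Mast cell genes rose most steeply: Cpa3 (chromosome 3, 20215620 to 20242181), which encodes mast cell carboxypeptidase A3, rose from 19.1 ± 11.9 to 8725 ± 1273 CPM. Cd34 (chromosome 1, 194938819 to 194961279), a surface protein of progenitors that mouse LT-HSCs largely lack, rose from 44.6 ± 12.5 to 522 ± 108 CPM. In the lists of the cell cycle, cholesterol synthesis, the erythroid lineage and the lymphoid lineage, 36 of 52, 6 of 24, 12 of 26 and 8 of 22 genes fell. With an estimated correlation the cholesterol list was called (adjusted p = 0.0393) and the other 3 were not (adjusted p = 0.133, 0.118 and 0.118). Of 14589 genes tested, 1107 were higher and 684 lower in AML1-ETO LT-HSCs. The 3 AML1-ETO values did not overlap the 4 control values for 4244 genes (29.1%), where chance gives 5.7%.

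In the list of mast cell, basophil and eosinophil genes, 14 of 20 measured members rose, 1 fell and 5 did not pass the test (14 and 1 adjusted over the list alone), with a median log2 fold change of 5.35, or 5.25 with genes without control counts set at their lower bound. The list stood apart from other genes by camera (adjusted p = 4.15e-15; adjusted p = 0.0137 with an estimated correlation). Cpa3 changed by a log2 fold of 8.84 ± 0.65 (adjusted p = 0.000582) and Il1rl1, the receptor of interleukin 33, by 5.17 ± 0.55 (adjusted p = 0.00174). Fcer1a, a chain of the high-affinity IgE receptor, stood at 44.4 ± 17.1 CPM and the mast cell protease gene Mcpt4 at 59.1 ± 28.8 CPM, both against 0 counts in control LT-HSCs, at least 906-fold and at least 1205-fold higher. Reads of Mcpt4 and of other mast cell proteases may be split between similar genes. The member that fell was Prg2, the eosinophil major basic protein gene, at −5.59.

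Genes of granulocyte-monocyte progenitors and of the primary granule also shifted upward: 12 of 31 rose and 1, the granule protease gene Prtn3, fell (13 and 3 adjusted over the list alone). Its median was 0.44 (camera adjusted p = 0.00328; adjusted p = 0.406 with an estimated correlation). Without AML1-ETO LT-HSC replicate 1 the camera adjusted p was 0.0835. Cd34 rose by 3.55 ± 0.27 (adjusted p = 0.000594), Srgn, the proteoglycan of secretory granules, by 1.95 ± 0.21 to 1718 ± 391 CPM, and Csf3r, the receptor of granulocyte colony-stimulating factor, by 3.15 ± 0.48 to 501 ± 55.6 CPM. Mpo, the myeloperoxidase gene, stood at 502 ± 63.2 against 74.5 ± 49.1 CPM. Prtn3 had a log2 fold change of −2.17. Among the immediate early genes, which respond to signalling and to cell dissociation, 11 of 37 rose and none fell (16 and 0 adjusted over the list alone). The list had a median of 1.26 (camera adjusted p = 0.000518; adjusted p = 0.549 with an estimated correlation). Rhob stood at 2713 ± 843 against 596 ± 148 CPM, Dusp2 at 1842 ± 690 against 226 ± 131 CPM, Dusp1 at 3541 ± 1045 against 866 ± 323 CPM and Btg2 at 1186 ± 770 against 270 ± 16.8 CPM.

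**Figure D2:**
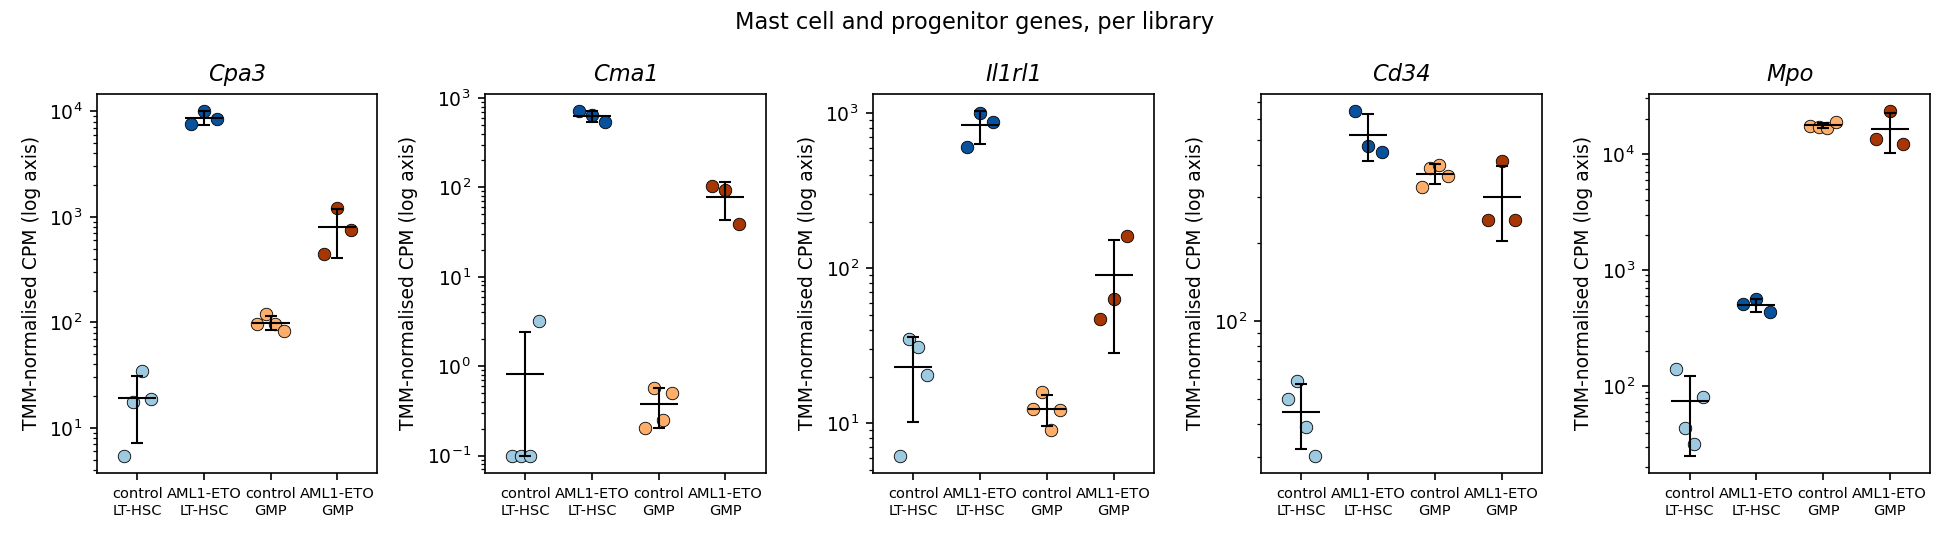
Cpa3, Cma1, Il1rl1, Cd34 and Mpo in TMM-normalised CPM on log axes, 1 point per library, with bars for the mean ± SD of each group and libraries without counts drawn at the lower end of the axis. Cpa3 averaged 8725 CPM in AML1-ETO and 19.1 CPM in control LT-HSCs, and 799 CPM in AML1-ETO and 98.7 CPM in control GMPs.

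Genes of the cell cycle and DNA replication fell together in AML1-ETO LT-HSCs, 36 of 52 lower and none higher (46 and 1 adjusted over the list alone). Over the whole list the median was −2.08 (camera adjusted p = 8.41e-29; adjusted p = 0.133 with an estimated correlation). The replication licensing factor Cdt1 stood at 27.6 ± 6.60 against 100.5 ± 21.1 CPM, the helicase genes Mcm5 at 61.3 ± 13.4 against 312 ± 122 CPM and Mcm2 at 92.9 ± 11.2 against 319 ± 94.4 CPM, and the thymidine kinase gene Tk1 at 17.8 ± 4.20 against 70.0 ± 16.9 CPM. In the list for cholesterol synthesis, 6 of 24 fell and none rose (11 and 0 adjusted over the list alone). The median was −1.15 (camera adjusted p = 1.92e-06; adjusted p = 0.0393 with an estimated correlation). Sqle, the squalene epoxidase gene, had a log2 fold change of −3.63 ± 0.37 and Cyp51, the lanosterol demethylase gene, of −3.93 ± 0.49.

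Lineage genes of red cells and lymphocytes were lower as well. The lymphoid and B cell list includes Ighm, Igkc and Jchain. Mixed-in cells in the control libraries are weighed below for immunoglobulin genes and were not tested as a source of these list falls. Of the erythroid list, 12 of 26 fell and none rose (16 and 1 adjusted over the list alone). Its median was −2.15 (camera adjusted p = 1.72e-11; adjusted p = 0.118 with an estimated correlation). The membrane skeleton genes Add2 and Ank1 had log2 fold changes of −6.85 ± 0.66 and −3.78 ± 0.47. The erythroid transcription factor gene Klf1 had −4.03 ± 0.49 and the carbonic anhydrase gene Car1 −6.56 ± 0.84. In the lymphoid and B cell list, 8 of 22 fell and 1 rose (13 and 3 adjusted over the list alone). The list had a median of −3.99 (camera adjusted p = 4.86e-07; adjusted p = 0.118 with an estimated correlation). The surrogate light chain gene Igll1 had 0 counts against 24.4 ± 13.5 CPM, at least 347-fold lower. Pou2af1 and Cd79a had −5.82 ± 0.80 and −5.99 ± 0.97, while Flt3, a receptor of multipotent and lymphoid progenitors, rose by 2.33 ± 0.36. Of the T and NK cell list, 5 of 19 fell and 1 rose (5 and 1 adjusted over the list alone). Across its members the median was −2.57 (camera adjusted p = 0.00943; adjusted p = 0.180 with an estimated correlation). Tcf7 had −6.80 ± 0.99, Il2rb −2.95 ± 0.43 and Lck −4.20 ± 0.78, and Trbc1 and Bcl11b fell as well. The 1 that rose was Prf1, the perforin gene, at 33.4 ± 28.9 CPM against 0 counts, at least 682-fold higher. Immunoglobulin genes took 2.26, 10.4, 1.92 and 2.76% of the counts of the control LT-HSC libraries and 0.0936, 0.0178 and 0.0380% of those of AML1-ETO LT-HSCs. Every control library lay above every AML1-ETO library. The difference of the means did not pass the test (exact permutation p = 0.0857, two-sided), on which the 10.4% of control LT-HSC replicate 2 weighs heavily. Of 36 immunoglobulin genes tested one by one, a group counted after the values were seen, 11 fell, among them Ighm, Igkc and Jchain, 18 were not called, and 7, all Ighv1 segments, rose from 0 counts to means of 2.33 to 23.2 CPM.

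Stem cell genes went both ways. In the LT-HSC identity list, 9 of 42 fell and 3 rose (12 and 5 adjusted over the list alone). The median was −1.0 (camera adjusted p = 0.00128; adjusted p = 0.549 with an estimated correlation), and the camera adjusted p was 0.0917 without control LT-HSC replicate 1. Mycn stood at 0.584 ± 1.01 against 90.2 ± 9.59 CPM, Ifitm1 at 2.83 ± 1.25 against 116 ± 70.1 CPM and Ctnnal1 at 5.15 ± 2.17 against 44.9 ± 15.9 CPM, while Hmga2, a chromatin protein gene of fetal stem cells, rose by 2.54 ± 0.30. Kit and Gata2 rose by 0.79 and 0.86. The genes Hlf and Procr, which mark stem cells, were not called, with log2 fold changes of 0.36 (adjusted p = 0.763) and −0.04 (adjusted p = 0.993). Both were named after their values were seen. Of 15 genes of the neutrophil secondary and tertiary granules, only Cybb was called, at −4.62 ± 0.85 (1 fell adjusted over the list alone). Its median was −2.34 (camera adjusted p = 0.0425; adjusted p = 0.466 with an estimated correlation). That list call was lost with DESeq2 size factors (0.0590) and without control LT-HSC replicate 1, 2 or 3 (0.108, 0.139 and 0.176).

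Among the lists of metabolism outside cholesterol and fatty acids, oxidative phosphorylation had 3 of 61 genes lower, Ndufa10, Sdhd and Ndufv1, and none higher (1 lower adjusted over the list alone). With all members the median was −0.47 (camera adjusted p = 1.09e-05; adjusted p = 0.549 with an estimated correlation). Glycolysis had 1 of 24 genes higher, the glucose transporter gene Slc2a3 (1.91 ± 0.31), and 3 lower, the monocarboxylate transporter gene Slc16a1, the hexokinase gene Hk2 and Ldhb (2 and 6 adjusted over the list alone). Over the whole list the median was 0.08, the mean −0.40 and the camera adjusted p 0.550. Ldhb, a lactate dehydrogenase gene, had 0 counts against 29.1 ± 22.1 CPM, at least 414-fold lower. Of 33 genes of eicosanoid metabolism, 4 rose, Alox5ap, Mgst2, Lpcat2 and Ltc4s, and 2 fell, Tbxas1 (−3.01 ± 0.45) and Ggt5, with a camera adjusted p of 0.624 (5 and 3 adjusted over the list alone). Ribosomal protein genes had a median of −0.19 with 1 of 64 lower and none higher (0 adjusted over the list alone; camera adjusted p = 0.0150; adjusted p = 0.739 with an estimated correlation), a call lost without AML1-ETO LT-HSC replicate 2 (0.0976) and without control LT-HSC replicate 2 (0.467).

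Leaving the fatty acid lists aside, the other lists were not called by camera in LT-HSCs, though fry called the transcription factors (adjusted p = 0.0428) and the t(8;21) leukaemia genes (adjusted p = 0.0111). Of the interferon response, 8 of 45 rose and 2 fell (8 and 3 adjusted over the list alone; camera adjusted p = 0.0962), with Trim30a and Ddx58 higher and Cmpk2 and Ifit2 lower. The list passed without AML1-ETO LT-HSC replicate 3 (0.0436) and without control LT-HSC replicate 2 (0.0160). Of the megakaryocyte list, 5 of 21 rose, Mpig6b, Treml1, Rab27b, Gp5 and Fli1, and 2 fell, Gp9 and Pf4 (6 and 2 adjusted over the list alone; adjusted p = 0.630). Of the myeloid transcription factors, 10 of 44 rose, among them Ikzf2 (2.88 ± 0.33), Lyl1 and Runx1, and 5 fell, Bcl11a, Hoxa5, Hoxa9, E2f2 and Irf4 (13 and 5 adjusted over the list alone; adjusted p = 0.146). Of the genes known from human t(8;21) leukaemia, 3 of 14 rose, Plcg1, Jup and Cd34, and 2, Bcl2 and Ccnd2, fell (4 and 4 adjusted over the list alone; adjusted p = 0.367), with a median of 0.66 and a mean of −0.31. Of the monocyte, macrophage and dendritic cell list, 2 of 22 rose, among them Flt3, and 1 fell, Ctss (2 and 1 adjusted over the list alone; adjusted p = 0.972; median −0.26, mean 0.09). Of the endothelial and stromal list, 2 of 10 rose, Pecam1 and Pdgfrb (2 and 1 adjusted over the list alone; adjusted p = 0.630). Its median was −0.66 although the test leaned upward. Of the 5 sex-linked genes measured, Xist was lower (1 adjusted over the list alone; adjusted p = 0.983; median 0.12, mean −0.91).

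The largest single changes in LT-HSCs were in genes without counts in the other genotype. Among the rises were Hcar2, a receptor of hydroxy acids (at least 3006-fold), Grm6 (1880-fold), Creb3l1 (1738-fold), Nlrp3 (1583-fold) and Frzb (1091-fold). The largest falls were in immunoglobulin V segments, Igkv15-103 (1761 ± 900 CPM against 0 counts, at least 25067-fold lower), Ighv7-1, Iglv1 and Ighv1-55, whose reads may be shared among similar segments. Gm36723 and Slc38a5 were at least 526-fold and 413-fold lower. The size for Gm36723 rests largely on control LT-HSC replicate 3, at 121 CPM against 5.52 to 12.1 CPM in the other control libraries.

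Of the 91 named genes called in LT-HSCs, 48 were called again without any 1 library and 43 were not. The 43, which include Mpo, Dusp1, Btg2, Mcm5, Mcm2, Lck, Prf1, Cybb, Hk2, Slc16a1, Nlrp3 and Iglv1, lost 42 calls without AML1-ETO LT-HSC replicate 2, 34 without replicate 1 and 25 without replicate 3. They lost 5, 6, 2 and 16 without control LT-HSC replicates 1 to 4. The share of higher genes was 51.7% (912 higher, 853 lower) with upper-quartile factors and 47.2% (1320 and 1475) with DESeq2, in place of 61.8%. With upper-quartile factors the median log2 fold change of all genes was −0.10 in place of 0.03. Genes with at least 1 count numbered 17310 ± 842 in AML1-ETO and 13970 ± 1423 in control LT-HSC libraries (exact permutation p = 0.0286), and genes at 1 CPM or more 13330 ± 140 and 13240 ± 1286 (p = 0.943 by the same exact test). Of the 1107 higher genes, 245 had no count in any control LT-HSC library. Of 7754 genes with a median of at least 20 CPM, 99 lay under 0.2 CPM in control LT-HSC replicate 3. The other control libraries had 1, 4 and 8 such genes, and the AML1-ETO libraries 6 to 10. Folds that rest on 0 control counts may thus be too large.

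In GMPs the comparison asks what the fusion changes in the progenitor that gives rise to granulocytes and monocytes. In the lists of mast cells and basophils, the interferon response, the immediate early response and neutrophil granules, 16 of 23, 21 of 44, 23 of 35 and 9 of 16 genes rose. With an estimated correlation the first 3 were called (adjusted p = 0.00443, 0.00799 and 0.0377) and the neutrophil list was not (adjusted p = 0.111). Lyz2, the lysozyme gene, rose from 133 ± 12.5 to 508 ± 98.4 CPM, Cd177, a neutrophil surface protein gene, from 5.35 ± 1.34 to 84.3 ± 32.5 CPM, and Gbp2 (chromosome 3, 142620602 to 142638008), an interferon-induced GTPase gene, from 6.98 ± 2.50 to 77.9 ± 24.1 CPM. Of 13981 genes tested, 765 were higher and 554 lower in AML1-ETO GMPs. The groups did not overlap for 3683 genes (26.3%), where chance gives 5.7%.

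Of the mast cell, basophil and eosinophil list, 16 of 23 rose and none fell (20 and 1 adjusted over the list alone). The median was 2.25 (camera adjusted p = 3.12e-27; adjusted p = 0.00443 with an estimated correlation). The mast cell chymase gene Cma1 stood at 78.9 ± 35.3 against 0.382 ± 0.181 CPM (7.66 ± 0.49; adjusted p = 0.00117). The basophil protease gene Mcpt8 stood at 483 ± 91.3 against 63.9 ± 15.5 CPM (2.92 ± 0.22; adjusted p = 0.00130). Cpa3 reached 799 ± 388 against 98.7 ± 15.1 CPM (3.02 ± 0.31; adjusted p = 0.00427). Tpsb2, a tryptase gene, stood at 22.3 ± 9.19 CPM against 0 counts, at least 539-fold higher. Of the interferon response list, 21 of 44 rose and none fell (29 and 0 adjusted over the list alone). Its median was 1.25 (camera adjusted p = 1.67e-22; adjusted p = 0.00799 with an estimated correlation). Gbp2 rose by 3.48 ± 0.33, Igtp by 2.43 ± 0.26 and Oasl2 by 2.87 ± 0.34.

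Immediate early genes moved with them, 23 of 35 higher and 1, Myc, lower (27 and 1 adjusted over the list alone). The list had a median of 1.34 (camera adjusted p = 1.56e-30; adjusted p = 0.0377 with an estimated correlation). The stress transcription factor gene Atf3 stood at 162 ± 17.9 against 17.7 ± 6.90 CPM, Mcl1 at 628 ± 97.8 against 261 ± 18.7 CPM, Ppp1r15a at 288 ± 51.5 against 107 ± 16.3 CPM and Ier5 at 140 ± 11.9 against 35.3 ± 10.5 CPM. Of the neutrophil secondary and tertiary granule list, 9 of 16 rose and none fell (13 and 0 adjusted over the list alone). Across its members the median was 2.95 (camera adjusted p = 1.64e-15; adjusted p = 0.111 with an estimated correlation). Cd177 rose by 3.98 ± 0.31, Lcn2 by 3.66 ± 0.40, S100a8 by 3.30 ± 0.40 and S100a9 by 5.46 ± 0.77. The list of GMP and primary granule genes was not called (camera adjusted p = 0.478; median −0.06, mean 0.06), with 3 of 34 higher, Lyz2 (1.94 ± 0.15), Csf2rb and Fcgr2b, and 2 lower, Elane, the neutrophil elastase gene, at 3076 ± 424 against 4928 ± 451 CPM, and Anxa3 (7 and 4 adjusted over the list alone). It was called without AML1-ETO GMP replicate 3 (0.0451).

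Genes of other lineages rose in AML1-ETO GMPs with a wide spread between the 3 libraries. Whether they were expressed in the GMPs or in other cells mixed into the libraries was not tested. Globin genes took 0.452, 0.00539 and 0.115% of their counts, against at most 6.18e-05% in control GMPs (exact permutation p = 0.0286, the smallest that 35 arrangements allow). Hbb-bs (chromosome 7, 103826534 to 103828096), a beta-globin gene whose reads may be shared with Hbb-bt, stood at 2065, 22.8 and 533 CPM. Of the erythroid list, 9 of 25 rose and none fell (19 and 0 adjusted over the list alone). The median was 3.74 (camera adjusted p = 6.86e-11; adjusted p = 0.412 with an estimated correlation). Of the megakaryocyte list, 7 of 18 rose and none fell (16 and 0 adjusted over the list alone). Its median was 3.15 (camera adjusted p = 9.82e-09; adjusted p = 0.412 with an estimated correlation), and Treml1 stood at 17.7, 11.4 and 355 CPM. Of the monocyte, macrophage and dendritic cell list, 9 of 24 rose and none fell (11 and 0 adjusted over the list alone). The list had a median of 1.16 (camera adjusted p = 0.00385; adjusted p = 0.590 with an estimated correlation). The antigen presentation gene Cd74 stood at 1127, 55.6 and 173 CPM, and the monocyte list was lost without AML1-ETO GMP replicate 1 (0.523).

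Of the LT-HSC identity list, 10 of 33 rose and 1, Kit, fell (13 and 2 adjusted over the list alone). Over the whole list the median was 1.46 (camera adjusted p = 0.000256; adjusted p = 0.501 with an estimated correlation, and 0.0805 by camera without AML1-ETO GMP replicate 3). Esam stood at 58.1 ± 71.8 against 0.254 ± 0.0951 CPM, Tek at 49.8 ± 62.9 against 1.24 ± 0.227 CPM, Mmrn1 at 48.6 ± 57.2 against 1.42 ± 0.838 CPM and Txnip at 344 ± 231 against 68.2 ± 13.6 CPM. The endothelial and stromal list had 3 of 5 members higher, Pecam1, Sparc and Kdr, and none lower (4 and 0 adjusted over the list alone). The median was 1.88 (camera adjusted p = 0.00373; adjusted p = 0.111 with an estimated correlation). Of the T and NK cell list, 2 of 8 rose, among them Tcf7 (2.34 ± 0.51), and none fell (5 and 1 adjusted over the list alone). Its median was 2.62 (camera adjusted p = 0.0205; adjusted p = 0.412 with an estimated correlation, and 0.0803 by camera without AML1-ETO GMP replicate 1). The lymphoid and B cell list was not called (adjusted p = 0.478; median 0.14, mean −0.28), with 1 of 9, Rag2, lower (1 adjusted over the list alone). Xist stood at 581, 1.03 and 500 CPM in the AML1-ETO GMP libraries and at 0.103 to 29.1 CPM in the control GMP libraries, while genes of the Y chromosome summed to 71.1, 258 and 143 CPM against 221 to 272 CPM. AML1-ETO GMP replicates 1 and 3 thus had the most Xist and also the largest globin shares. A difference in sex or pooling between the libraries was not tested as a source of the rises.

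**Figure D3:**
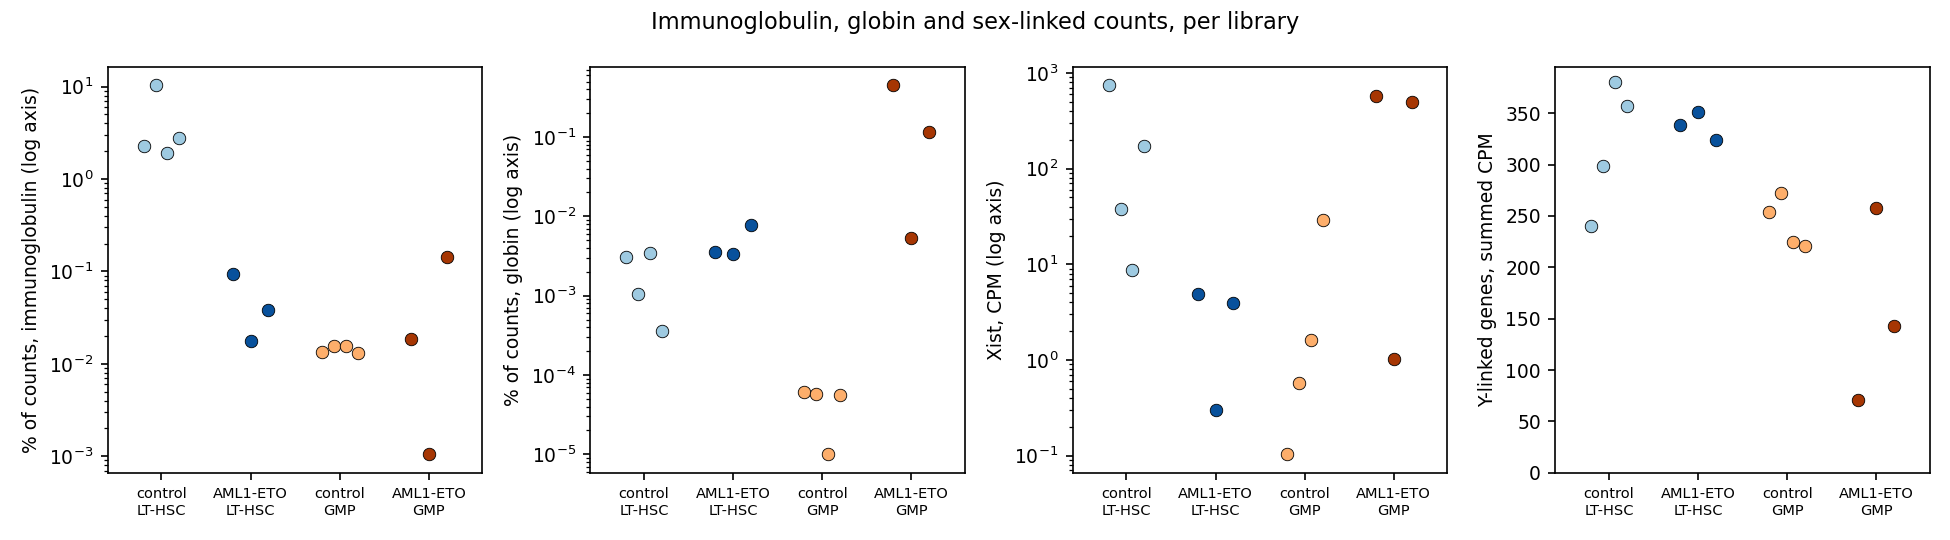
Percent of counts from immunoglobulin and globin genes and CPM of Xist on log axes (a value of 0 is drawn at the lower end), and the summed CPM of Y-linked genes on a linear axis, 1 point per library in 4 groups. The 4 control LT-HSC libraries have 1.92 to 10.4% immunoglobulin counts, and AML1-ETO GMP replicates 1 and 3 have the highest globin shares, 0.452 and 0.115%.

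Cell cycle genes were slightly lower in AML1-ETO GMPs, with 11 of 52 lower and 2, Cdc20 and Ube2c, higher (16 and 4 adjusted over the list alone) and a median of −0.17 (camera adjusted p = 0.0326; adjusted p = 0.590 with an estimated correlation). Mcm2 stood at 304 ± 7.82 against 478 ± 22.6 CPM (−0.65 ± 0.08), and Hells, Mcm6 and Fen1 were lower as well. The list was lost with DESeq2 size factors (0.0527) and without AML1-ETO GMP replicate 2 (0.263), AML1-ETO GMP replicate 3 (0.173) or control GMP replicate 4 (0.0530). Ribosomal protein genes had a median of −0.20 with 3 of 64 lower, among them Rpl22 and Rps29, and none higher (0 adjusted over the list alone; camera adjusted p = 5.26e-05; adjusted p = 0.590 with an estimated correlation). Oxidative phosphorylation genes had a median of −0.17 with 1 of 61 lower, Ndufs1, and none higher (0 adjusted over the list alone; camera adjusted p = 0.0205; adjusted p = 0.655 with an estimated correlation), lost without AML1-ETO GMP replicate 3 (0.0805) or control GMP replicate 3 (0.136). Cholesterol synthesis had a median of −0.28 with none of 24 genes called (0 adjusted over the list alone; camera adjusted p = 0.0269; adjusted p = 0.437 with an estimated correlation), lost without AML1-ETO GMP replicate 2 (0.101), AML1-ETO GMP replicate 3 (0.0630) or control GMP replicate 3 (0.0607). Its lead gene Sqle had 24.4 ± 7.27 against 40.5 ± 7.38 CPM (adjusted p = 0.114).

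Of the eicosanoid list, 3 of 30 rose, Alox12, Hpgds, the prostaglandin D synthase of mast cells, and Ptgs1, and none fell (3 and 0 adjusted over the list alone). The list had a median of 0.26 (camera adjusted p = 0.0295; adjusted p = 0.412 with an estimated correlation, and 0.372 and 0.161 by camera without AML1-ETO GMP replicates 1 and 3). Of the myeloid transcription factors, 7 of 42 rose, among them Bach2 and Cebpb, and 2 fell, Cbfb and Myc, the latter at 200 ± 57.4 against 430 ± 36.1 CPM (11 and 3 adjusted over the list alone). Across its members the median was 0.17 (camera adjusted p = 0.0413; adjusted p = 0.412 with an estimated correlation). That call was lost without AML1-ETO GMP replicates 1 (0.0857) and 3 (0.526) and control GMP replicate 1 (0.0862). Glycolysis was not called (adjusted p = 0.907; median −0.05, mean 0.09), with 2 of 24 higher, the lactate transporter gene Slc16a3 (1.56 ± 0.19) and Slc2a3, and 3 lower, Pfkl, Pgam1 and Pgk1 (3 and 4 adjusted over the list alone). The genes known from t(8;21) leukaemia were not called by camera (adjusted p = 0.134; 0.0357 by fry), with 2 of 12 higher, Jup (2.33 ± 0.22) and Id1 (2.43 ± 0.32), and none lower (2 and 0 adjusted over the list alone). None of 5 sex-linked genes was called (1 and 1 adjusted over the list alone; adjusted p = 0.329; median −0.53, mean 0.51), and the list passed without AML1-ETO GMP replicate 2 (0.0190).

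The largest rises in GMPs, among genes whose groups did not overlap, were in Hbb-bs, Hba-a1, Hbb-bt, Hba-a2 (at least 408-fold), Tpsb2, Sema6d (at least 380-fold), Tpsg1 (at least 285-fold) and Ubd (at least 253-fold). The largest falls were at low levels: Xlr3b, a gene with close copies, stood at 8.92 ± 1.26 CPM in control GMPs and at 0 counts in AML1-ETO GMPs, at least 143-fold lower. Nrg1, Disc1, Irak1bp1, Sdc1, 4930447C04Rik and Zdhhc23 were at least 51.2-fold to 73.9-fold lower. Of the 554 lower genes, 253 (45.7%) lay under a mean of 10 CPM and 236 had no count in any AML1-ETO GMP library. Genes with at least 1 count numbered 14150 ± 710 in AML1-ETO and 19130 ± 371 in control GMP libraries (exact permutation p = 0.0286). At 1 CPM or more the means lay the other way, at 12910 ± 323 and 12680 ± 127 genes (p = 0.286 by the same exact test).

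Of the 82 named genes called in GMPs, 23 were called again without any 1 library, among them Atf3, Cd177, Cma1, Cpa3, Esam, Gbp2, Id1, Ier5, Igtp, Jup, Lcn2, Lyz2, Mcl1, Mcm2, Mcpt8, Oasl2, Ppp1r15a, Runx1t1, S100a8, Slc16a3, Tpsb2 and Xlr3b. The other 59 lost their call without control GMP replicate 1, and 48, 58 and 58 of them without control GMP replicates 2 to 4. Without control GMP replicate 1 there were 123 genes higher and 12 lower, without replicate 2 there were 182 and 27, without replicate 3 116 and 15, and without replicate 4 121 and 13, while leaving out AML1-ETO GMP replicate 2 gave 1550 and 1964.

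**Figure D4:**
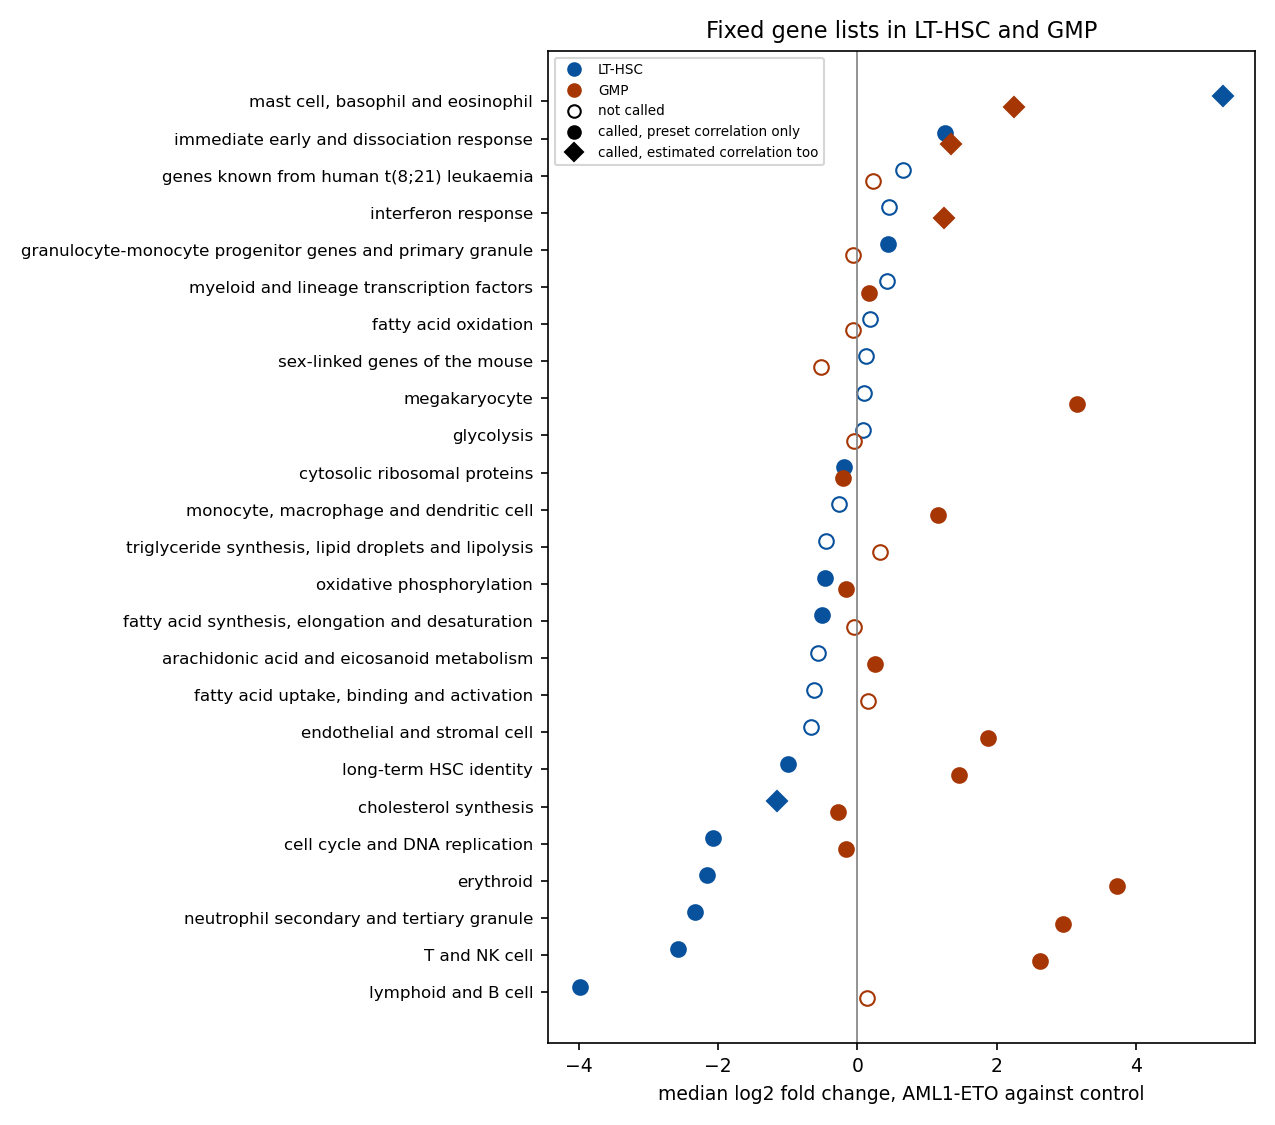
Median log2 fold change of AML1-ETO against control for each of the 25 gene lists in LT-HSCs (blue) and GMPs (red), with genes without counts in a group set at their bound; filled points passed camera with the preset correlation, diamonds also with an estimated correlation, and open points did not pass. The mast cell list lies highest in LT-HSCs (5.25) and the lymphoid and B cell list lowest (−3.99), while in GMPs the erythroid list lies highest (3.74).

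Fatty acid genes were examined because the title of the series names their metabolism. In LT-HSCs, 3 of 27 measured genes of synthesis, elongation and desaturation fell and none rose (7 and 1 adjusted over the list alone). The median was −0.51 (camera adjusted p = 0.00133; adjusted p = 0.0932 with an estimated correlation). Fads2 (chromosome 19, 10062765 to 10101746), the delta-6 desaturase gene, stood at 4.66 ± 3.49 against 86.9 ± 24.9 CPM (−4.23 ± 0.54; adjusted p = 0.00326). Fads1, the delta-5 desaturase gene, stood at 48.0 ± 13.5 against 117 ± 26.2 CPM (−1.28 ± 0.27; adjusted p = 0.0204). Hacd4, a dehydratase gene of elongation, stood at 12.3 ± 7.96 against 54.8 ± 17.2 CPM (−2.16 ± 0.55; adjusted p = 0.0388). Acss2, which makes acetyl-CoA from acetate, had −1.26 ± 0.35 (adjusted p = 0.0507). The mean log2 CPM of the list was 4.68 ± 0.0324 in AML1-ETO and 5.37 ± 0.203 in control LT-HSCs, a difference of −0.690 with all 3 AML1-ETO values below the 4 control values (exact permutation p = 0.0286, two-sided, the smallest that 35 arrangements allow). Adjusted over 8 tests it was 0.229. Without AML1-ETO LT-HSC replicate 2, Fads2 kept its call and Fads1 and Hacd4 did not.

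The other fatty acid lists were not called by camera in LT-HSCs. By fry, which tests whether a list's genes move one way and does not compare them with other genes, oxidation was called upward (adjusted p = 0.00794) and uptake downward (adjusted p = 0.00850), while triglycerides were not called (0.474). Of oxidation, 2 of 37 rose and none fell (1 and 0 adjusted over the list alone): Ppard, a lipid-sensing nuclear receptor gene, by 1.5 ± 0.26, and Acadl, a long-chain acyl-CoA dehydrogenase gene, by 0.74 ± 0.20. The camera adjusted p was 0.634, with a median of 0.18 and a mean of −0.11, and the list score differed by 0.125 (exact permutation p = 0.286). Of uptake, binding and activation, 1 of 20 rose, Acbd3, and 2 fell, among them Acsl3, an acyl-CoA synthetase gene (2 and 2 adjusted over the list alone). Its median was −0.62 (camera adjusted p = 0.0792, and 0.0401 without AML1-ETO LT-HSC replicate 1), and its score differed by −0.556 (exact permutation p = 0.20). Of triglycerides and lipid droplets, 1 of 23 rose, G0s2, an inhibitor of lipolysis, at 1.41 ± 0.786 CPM against 0 counts, and none fell (0 and 0 adjusted over the list alone). The list had a median of −0.46 (camera adjusted p = 0.322) and a score difference of −0.211 (exact permutation p = 0.543).

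In GMPs none of the 4 fatty acid lists was called by camera, and fry called triglycerides upward (adjusted p = 0.0261). Of synthesis, 1 of 27 fell, Acaca, the acetyl-CoA carboxylase gene, at 34.1 ± 9.53 against 68.2 ± 5.03 CPM (−1.0 ± 0.19; adjusted p = 0.0228). The 1 that rose was the desaturase gene Scd1, at 25.1 ± 23.7 against 2.03 ± 1.87 CPM (3.62 ± 0.91; adjusted p = 0.0443). There was 1 fall and 0 rises adjusted over the list alone. The camera adjusted p was 0.810, with a median of −0.05 and a mean of 0.28, and the score difference 0.153 (exact permutation p = 0.229). Of oxidation, 1 of 37 rose (0 adjusted over the list alone; camera adjusted p = 0.799; median −0.07; score difference −0.0389, exact permutation p = 0.714). Of uptake, 2 of 21 rose, Slc27a3 (1.67 ± 0.32) and Acsbg1 (2 and 0 adjusted over the list alone; camera adjusted p = 0.215, and 0.0495 without AML1-ETO GMP replicate 2; score difference 0.304, exact permutation p = 0.229). Of triglycerides and lipid droplets, 2 of 25 rose, the lipid droplet coat gene Plin2 (0.92 ± 0.17) and Lpin2 (2 and 0 adjusted over the list alone). Over the whole list the median was 0.33, and the score differed by 0.283 (exact permutation p = 0.0571). Its camera adjusted p was 0.0534, and 0.0450 and 0.0455 without AML1-ETO GMP replicates 2 and 3. Of these fatty acid genes in GMPs, Acaca, Scd1, Slc27a3, Acsbg1, Plin2 and Lpin2 each lost the call without any 1 control GMP library.

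Whether the AML1-ETO effect differed between the cell types was tested in 1 fit of all 14 libraries. Of 16116 genes tested, the effect was higher in GMPs for 552 and lower in GMPs for 469. The list for fatty acid synthesis was more positive in GMPs, with 5 of 29 genes higher, Fads2, Hacd4, Acss2, Scd1 and Srebf1, and none lower (7 and 0 adjusted over the list alone), a median difference of 0.35 and a camera adjusted p of 0.000830 (adjusted p = 0.0320 with an estimated correlation). Cholesterol synthesis (4 of 24 higher, among them Sqle, Cyp51 and Sc5d, median 0.96, camera adjusted p = 1.26e-05; adjusted p = 0.0263 with an estimated correlation), the cell cycle (34 of 52 higher, median 2.02, 3.71e-41; adjusted p = 0.0320 with an estimated correlation) and the erythroid list (21 of 26 higher, median 7.31, 3.34e-25; adjusted p = 0.0347 with an estimated correlation) differed the same way. No member of the 3 was lower (5, 43 and 25 higher and 0, 1 and 0 lower adjusted over the list alone). The erythroid rise in GMPs varied widely between AML1-ETO libraries, and mixed-in cells were not tested as its source. The mast cell list was more positive in LT-HSCs, with 8 of 26 lower and 1, Prg2, higher in GMPs (10 and 2 adjusted over the list alone), a median of −2.28 and a camera adjusted p of 4.05e-06 (adjusted p = 0.0263 with an estimated correlation). Among 11 further lists called with the preset correlation alone were fatty acid uptake (1 of 26 higher and none lower, 6 and 0 adjusted over the list alone, camera adjusted p = 0.0443; adjusted p = 0.0951 with an estimated correlation) and triglycerides (2 of 26, Plin2 and Lpin2, higher and none lower, 4 and 1 adjusted over the list alone, camera adjusted p = 0.0344; adjusted p = 0.0951 with an estimated correlation). Oxidation was not called (0.820). The uptake call was lost without any 1 control LT-HSC library (0.0533 to 0.0892), without AML1-ETO GMP replicate 1 (0.127) and with DESeq2 size factors (0.0509). The triglyceride call was lost without AML1-ETO LT-HSC replicate 3 (0.0551), control LT-HSC replicate 2 (0.0738) or AML1-ETO GMP replicate 1 (0.0888).

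Of the other 9 lists called with the preset correlation alone, 8 were more positive in GMPs. These were LT-HSC identity (15 of 42 higher and 2, Kit and Cd27, lower; camera adjusted p = 2.86e-08; adjusted p = 0.275 with an estimated correlation), neutrophil granules (10 of 18 higher; 1.65e-07; adjusted p = 0.0523 with an estimated correlation), lymphoid and B cells (10 of 24 higher; 1.10e-06; adjusted p = 0.0951 with an estimated correlation) and megakaryocytes (6 of 21 higher; 1.13e-06; adjusted p = 0.285 with an estimated correlation). The same holds for the interferon response (5 of 45 higher, Gbp2, Ifit2, Ifih1, Cmpk2 and Irf7; camera adjusted p = 9.96e-06; adjusted p = 0.285 with an estimated correlation), oxidative phosphorylation (2 of 61 higher, Ndufa10 and Sdhd; 1.14e-05; adjusted p = 0.416 with an estimated correlation), T and NK cells (6 of 22 higher and 1, Prf1, lower; 0.00213; adjusted p = 0.253 with an estimated correlation) and immediate early genes (2 of 37 higher, Socs3 and Nr4a1, and 2 lower, Myc and Rhob; 0.0348; adjusted p = 0.630 with an estimated correlation). Adjusted over the list alone, 22, 14, 14, 11, 11, 2, 9 and 4 members of these 8 lists were higher, and 2, 0, 2, 0, 1, 0, 1 and 2 lower. The list of GMP and primary granule genes was more positive in LT-HSCs, with 9 of 34 lower in GMPs and 2, Lyz2 and Elane, higher (13 and 5 adjusted over the list alone; camera adjusted p = 0.00609; adjusted p = 0.285 with an estimated correlation). It was lost without AML1-ETO LT-HSC replicate 1 (0.0891) or AML1-ETO GMP replicate 3 (0.0606). The immediate early list was lost without AML1-ETO LT-HSC replicate 3 (0.414), control LT-HSC replicates 1 (0.168) or 2 (0.149), AML1-ETO GMP replicate 3 (0.0964) or control GMP replicate 4 (0.103). By fry the neutrophil (adjusted p = 0.00976), lymphoid (0.0220) and GMP (0.0243) lists were called among these 9. The lymphoid difference carries the limit of the fall in LT-HSCs, where mixed-in cells in the control libraries were not tested as its source.

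Among single genes, Cd34, which rose in LT-HSCs, differed by −3.76 ± 0.34 (adjusted p = 0.000333). Tent5a (−3.77 ± 0.38), Lat2, an adaptor of mast and B cells (−3.42 ± 0.35), and BC035044 (−3.04 ± 0.32) were likewise more positive in LT-HSCs, as was Creb3l1, which had no counts in control LT-HSCs. The effect was more positive in GMPs for Tnfaip2 (3.96 ± 0.39), Irak3 (3.45 ± 0.40), the basement membrane collagen gene Col4a1 (7.75 ± 0.82) and Tcf7 (9.24 ± 1.07), and for Gbp4, which stood at 3.92 against 58.0 CPM in LT-HSCs and at 6.34 CPM against 0 counts in GMPs. Runx1 differed by −1.03 ± 0.25 (adjusted p = 0.0265), a call lost without AML1-ETO LT-HSC replicate 2, AML1-ETO GMP replicate 3 or control GMP replicate 2, 3 or 4, with an adjusted p of up to 0.0870. Runx1t1 differed by −0.11 ± 1.19 (adjusted p = 1.0).

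GMPs were compared with LT-HSCs within each genotype in the same fit, as a check of the sorted populations and of what separates them. In control mice, 31 of 34 GMP genes were higher in GMPs and none lower (33 and 0 adjusted over the list alone; median 4.88, camera adjusted p = 9.15e-42; adjusted p = 0.00169 with an estimated correlation), and 33 of 42 LT-HSC identity genes were lower and none higher (36 and 0 adjusted over the list alone; median −4.87, camera adjusted p = 5.92e-25; adjusted p = 0.0634 with an estimated correlation). Mpo changed by 7.97 ± 0.47, Prtn3 by 5.87 ± 0.47, Cd34 by 3.12 ± 0.24 and Calr by 2.35 ± 0.19, and Csf1r and Cebpe, without counts in control LT-HSCs, were at least 4139-fold and 2132-fold higher. Falls were −8.56 ± 0.67 for Fgd5, −7.30 ± 0.97 for Esam, −6.82 ± 0.78 for Ly6a, −5.76 ± 0.83 for Mmrn1, −4.47 ± 0.47 for Hlf and −3.22 ± 0.46 for Mllt3. Among genes without counts in LT-HSCs, Epx, the eosinophil peroxidase gene, Prss34, a basophil protease gene, and Mefv were also at least 9134-fold, 2063-fold and 1683-fold higher. The largest falls were in Igkc (at least 202930-fold) and the V segments Igkv15-103, Igkv14-126, Ighv7-1 and Ighv11-2. In all, 2247 genes were higher and 1702 lower in GMPs. With DESeq2 size factors the share of higher genes was 44.9% (1698 and 2087) in place of 56.9%, and the median of all genes −0.12 in place of 0.02. With upper-quartile factors it was 47.4% (1782 and 1980).

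In AML1-ETO mice, 26 of 34 GMP genes were higher and none lower (27 and 1 adjusted over the list alone; median 4.34, camera adjusted p = 5.97e-23; adjusted p = 0.00706 with an estimated correlation). Of the LT-HSC identity genes, 11 of 42 were lower and 1, Ifitm1, higher (12 and 1 adjusted over the list alone). The median was −0.98, or −0.83 with genes at 0 set at their bound (camera adjusted p = 2.46e-05; adjusted p = 0.357 with an estimated correlation). Prtn3 changed by 7.70 ± 0.59, Igsf6 by 7.30 ± 0.74, Cebpe by 6.41 ± 0.45, Anxa3 by 6.40 ± 0.57, Mpo by 5.18 ± 0.48 and Lyz2 by 3.14 ± 0.27. Falls were −3.92 ± 0.57 for Fgd5, −4.52 ± 0.54 for Hlf, −4.95 ± 0.79 for Ly6a, −1.95 ± 0.18 for Kit, −1.97 ± 0.39 for Cd27 and −1.70 ± 0.36 for Gata2. Elane and Epx, without counts in AML1-ETO LT-HSCs, were at least 48647-fold and 46332-fold higher, Prg3, Mefv and Abcd2 at least 3168-fold, 1186-fold and 1178-fold higher, and Adamtsl1, Prf1, Slc16a12, Ppp1r14c and Luzp2, without counts in AML1-ETO GMPs, at least 224-fold to 560-fold lower. In all, 2031 genes were higher and 1474 lower in GMPs. The share of higher genes was 57.9%, but 49.7% (1722 and 1744) with DESeq2 size factors and 48.5% (1670 and 1770) with upper-quartile factors. Without AML1-ETO LT-HSC replicate 2 the calls of Ppp1r14c, Luzp2 and Runx1 were lost, the last with an adjusted p of 0.0762 (−0.76 ± 0.19 and adjusted p = 0.0111 with all libraries). With upper-quartile factors the median of all genes moved from 0 to −0.11.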

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

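The tests of mast cell and basophil markers, of single immunoglobulin genes counted as a group, of class-switched antibody genes, of lost transcripts as a source of the mast cell pattern, of a single odd control library and of low abundance with a filter of 10 CPM were chosen after the results were seen; the tests of plasma cell markers and of other splits of the samples were set before. The 6 single libraries below come from 56 tests of groups of 4 samples, where chance gives about 2.8 such cases, and each is given with its gap to the nearest library as a share of the range. All 6 lie above the critical value of Dixon's test.

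The 10 most abundant genes took 11.3% of the counts of control LT-HSC replicate 2 against 4.78 to 5.38% in the other 3 (gap 0.908), and immunoglobulin genes took 10.4% against 1.92 to 2.76% (gap 0.901). Control LT-HSC replicate 3 had a fatty acid oxidation score of 4.96 against 5.26 to 5.29 (gap 0.936) and Gm36723 at 121 CPM against 5.52 to 12.1 CPM (gap 0.943). In control GMP replicate 2 the 10 most abundant genes took 5.92% against 6.23 to 6.25% (gap 0.939). Xist stood at 29.1 CPM in control GMP replicate 4 against 0.103 to 1.61 CPM in the other 3 (gap 0.948).

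The AML1-ETO effect differed between the cell types by the interaction test of edgeR, with the log2 effect in GMPs minus that in LT-HSCs at 3.96 for Tnfaip2, 7.75 for Col4a1, 9.24 for Tcf7, 3.45 for Irak3, −3.76 for Cd34, −3.77 for Tent5a, −3.42 for Lat2, −3.04 for BC035044 and −1.03 for Runx1. For Gbp4 and Creb3l1 the fitted differences of 13.55 and −12.32 rest on a group without counts and are not sizes. The median differences of the lists that also held with an estimated correlation were 0.35 for fatty acid synthesis, 0.96 for cholesterol synthesis, 2.02 for the cell cycle, 7.31 for the erythroid list and −2.28 for the mast cell list.

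Of 36 immunoglobulin genes tested in LT-HSCs, 11 were lower and 7, Ighv1 segments at 2.33 to 23.2 CPM against 0 counts in controls, higher in AML1-ETO, and the difference in their whole share of counts did not pass its test (exact permutation p = 0.0857). A single odd or mislabelled library as the source of the higher control shares is argued against, since 4 of the 4 control libraries exceeded the highest AML1-ETO library. Plasma cells, or their RNA, in the control LT-HSC libraries remain a candidate explanation: 12 plasma cell markers had a median log2 fold change of −3.03, but 3 of them were called, Mzb1 (64.0 against 1.56 CPM), Txndc5 (300.2 against 74.7 CPM) and Irf4, and 9 were not, among them Xbp1 (−0.42), Prdm1 (−0.27), Edem2 (0.62) and Tnfrsf13b (0.84). A sort of LT-HSCs would be expected to remove such cells, and the gates are not in the labels. Lymphoid priming of the stem cells themselves is argued against as the whole source in 3 of the 4 control libraries, replicates 1 to 3. There class-switched heavy chain genes, which stem cells do not make, held 26678, 73619 and 3177 counts against at most 2 in AML1-ETO LT-HSCs. Such priming stays open in the 1 with 0 such counts, replicate 4. That library still held 64239 counts of Igkc, 10733 of Jchain and 101735 of V segments. The AML1-ETO LT-HSC libraries held at most 1874, 570 and 4645. Class-switched counts were not confined to control LT-HSCs. AML1-ETO GMP replicate 3 held 10092 of them, all of Igha, with 3823 counts of Igkc and 1599 of Jchain. Every other GMP library held at most 1 class-switched count.

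Mast cell and basophil genes were higher in AML1-ETO LT-HSCs. Loss of transcripts from the control libraries was looked at over the 80 pairs of a measured member and a control library. The control library lay under 0.1 of the AML1-ETO mean in 76.3% of them. Random lists of genes at matched AML1-ETO levels gave 12.5% in the median and 32.5% in the highest of 10000. The mast cell list was picked after its rise was seen, so its share largely restates that rise. Loss that strikes genes of a level alike would not set a list so far apart, but loss of particular transcripts was not tested. Basophils like those in the GMP libraries are argued against as the source of the whole pattern, since Mcpt8, at 60.5 and 64.7% of the Cpa3 level in AML1-ETO and control GMPs, reached at most 1.08% in an AML1-ETO LT-HSC library, and Prss34 (102% and 97.5% in GMPs) at most 0.0131%, although the scarcer Cd200r3 (1.95 and 1.55%) reached 0.379% on average. Mature mast cells stay open, since Cma1 reached 7.25% of the Cpa3 level (6.38 to 9.27%). A mast cell program in stem cells that carry the fusion may be a biological explanation, and these bulk libraries do not separate it from a few mixed-in progenitors.

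Calls at low abundance leaned the way of the libraries with more genes at 1 count or more. Such genes were fewer in AML1-ETO than in control GMPs (14150 against 19130) and more in AML1-ETO than in control LT-HSCs (17310 against 13970), while genes at 1 CPM or more numbered 12910 against 12680 in GMPs (exact permutation p = 0.286) and 13330 against 13240 in LT-HSCs (p = 0.943 by the same exact test). Transcripts of low abundance lost from the libraries with fewer genes at 1 count may account for a part of the lower genes in GMPs and of the higher genes in LT-HSCs. With a filter of a mean of 10 CPM, 26.6% of called genes were lower in AML1-ETO GMPs (251 of them in place of 554, with 692 higher in place of 765). In LT-HSCs 49.5% were higher in AML1-ETO (803 of them in place of 1107), in part because the lower genes rose from 684 to 818. Both shares lay between the bounds set for and against this explanation. Input amount, library kit and batch are not in the labels by sample and cannot be told apart from the groups.

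Other splits of the samples were tried to see whether chance can be excluded. For LT-HSCs, GMPs and control mice, 1 of 35 splits, the real one, gave as many genes higher or lower (1107 and 684, 765 and 554, 2247 and 1702), and the highest of the other splits gave 0. This is the smallest share that 35 splits allow, so chance can be excluded at 0.05 and no further, and only for the spread between these libraries, which the labels do not call separate mice. Every other split mixes the real groups and carries their difference in its spread, so its 0 genes do not measure how many calls chance makes. For the difference between cell types, 1 of 100 drawn splits, the real one, gave as many (552 and 469, highest other 50). For AML1-ETO mice, 10 splits are too few for a share under 0.05 (real counts 2031 and 1474, highest other 1).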

How the results depend on the processing

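The filter of a mean of 10 CPM, the protein-coding genes alone, and leaving out immunoglobulin genes or pairs of libraries were chosen after the results were seen; the other alternatives were set before. Over all alternatives, the calls of single named genes kept their direction and side of the threshold in 4703 cases, were lost in 656, were gained in 121 and turned in 0; those of lists kept it in 1367, were lost in 133, gained in 49 and turned in 1. That was the lymphoid and B cell list in GMPs, which was called in the opposite direction without AML1-ETO GMP replicate 2 (camera adjusted p = 0.00796, against 0.478 with all libraries and up to 0.985 without another library). Where counts of calls moved by over 1.5 times the cause was not tested. Fewer samples or fewer genes enter where libraries are left out or a filter is raised. That alone does not account for counts that rose, as they did without AML1-ETO GMP replicate 2.

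In LT-HSCs (1107 higher, 684 lower), voomWithQualityWeights gave 1939 and 1432, the fit of all 14 samples 1669 and 1497, and DESeq2 1320 and 1475, which turns the majority. Leaving out 1 library gave 223 to 1373 higher and 111 to 1003 lower, lowest without AML1-ETO LT-HSC replicate 2 and highest without control LT-HSC replicate 3; AML1-ETO LT-HSC replicates 1 and 3 and control LT-HSC replicate 4 also moved the counts, to 352 and 182, 404 and 285, and 714 and 433. Without immunoglobulin genes there were 1063 higher and 669 lower, of which 1044 and 665 were shared, and without control LT-HSC replicates 2 and 3 there were 1079 and 654, of which 766 and 440 were shared.

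In GMPs (765 higher, 554 lower), DESeq2 gave 1371 and 937, the fit of all 14 samples 394 and 64, and that fit without AML1-ETO GMP replicates 1 and 3 gave 116 and 70, where the 1 sample left is assumed to vary like the other groups. The lower genes fell to 260 with no filter, 267 with a mean of 50 counts, 251 with a mean of 10 CPM, 293 with a log2 fold change over 1 and 47 with voomWithQualityWeights. Leaving out 1 library gave 116 to 1550 higher and 12 to 1964 lower: 123 and 12, 182 and 27, 116 and 15, and 121 and 13 without control GMP replicates 1 to 4, and 1258 and 1219, 1550 and 1964, and 913 and 959 without AML1-ETO GMP replicates 1 to 3. The test gives both groups 1 spread per gene, while replicates correlated by 0.983 to 0.986 in control and by 0.847 to 0.868 in AML1-ETO GMPs. P-values in GMPs may be too small for that reason, which was not tested.

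For the difference between cell types (552 higher, 469 lower in GMPs), DESeq2 gave 1090 higher, voomWithQualityWeights 734 lower, the filter of 10 CPM 305 lower, leaving out control LT-HSC replicates 2 and 3 725 lower, and leaving out AML1-ETO GMP replicates 1 and 3 119 and 113. Leaving out 1 library gave 235 to 735 and 236 to 742, lowest without AML1-ETO LT-HSC replicate 2 and highest without control LT-HSC replicate 1. Without AML1-ETO LT-HSC replicate 1 there were 333 higher, and without control GMP replicates 1 to 4 there were 342 and 282, 328 and 258, 349 and 297, and 344 and 284. In control mice (2247 and 1702), a log2 fold change over 1 gave 1315 higher, the filter of 10 CPM 1404 higher and DESeq2 2676 lower. Leaving out 1 library gave 1103 to 2092 lower, with the fewest without control GMP replicate 3. In AML1-ETO mice (2031 and 1474), leaving out GMP replicates 1 and 3 gave 1211 and 777, and leaving out 1 library 1294 to 1901 and 798 to 1397, with the fewest without AML1-ETO LT-HSC replicate 2 and 982 and 951 lower without AML1-ETO LT-HSC replicate 3 and AML1-ETO GMP replicate 1.

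With an estimated correlation, camera called 2 lists in LT-HSCs, 3 in GMPs, 5 for the difference, 2 in control mice and 4 in AML1-ETO mice, and fry called 12, 7, 8, 17 and 19. The triglyceride score in GMPs was 0.187 higher with members of at least 50 counts (exact permutation p = 0.0286). The fatty acid synthesis score in LT-HSCs differed by −0.753 to −0.607 without 1 library, where too few arrangements remain for the exact test to pass. Depth left levels under 0.0413 to 0.0702 CPM, 3 counts over a group, out of sight, and such genes have bounds in place of folds.

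Labels number the replicates but do not say that a number marks a shared animal or day. Deviations from the group means correlated by −0.0388 to 0.161 (mean 0.0446) between LT-HSCs and GMPs of the same number and genotype. Between AML1-ETO and control of the same number and cell type they correlated by −0.0765 to 0.0359 (mean −0.0166). Within AML1-ETO mice each library correlated best with its own number across cell types (0.0910, 0.161 and 0.109), a hint from the data and not from the design, and within control mice this was not so. Among control GMPs, each AML1-ETO LT-HSC library also correlated best with its own number (0.0603, 0.0676 and 0.0907). Control LT-HSCs did not do so among AML1-ETO GMPs. These low values leave open whether the numbers pair some of the samples. With the replicate number as a block, 312 and 213 genes were called in LT-HSCs, 107 and 5 in GMPs, and 300 and 208 for the difference. Among the lists of AML1-ETO against control, the block ended the cell cycle call in GMPs (0.149) and gained the interferon list in LT-HSCs (0.0448) and triglycerides in GMPs (0.0409). For the difference it ended the call of the GMP list (0.0922).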

Other observations

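The genes in this part and the overlap of the calls were chosen after the results were seen. Some genes were called in both AML1-ETO cell types in the same direction. Lilr4b and Lilrb4a, related receptor genes of myeloid and mast cells, rose by log2 folds of 8.03 and 7.57 in LT-HSCs and of 4.55 and 4.72 in GMPs (adjusted p of edgeR 0.00122 and 0.00455 in LT-HSCs, 0.00117 and 0.00194 in GMPs). Their reads may be shared between such similar genes. The complement gene C4b stood at 712 ± 340 against 7.75 ± 4.26 CPM in LT-HSCs and at 391 ± 100 against 2.28 ± 1.29 CPM in GMPs. Csf2rb2, a receptor chain of interleukin 3, rose by 3.70 and 2.30, Cd274, the ligand of PD-1, by 2.94 and 1.70, and Eng, the endoglin gene, by 1.59 and 1.52. Tnfaip3, a feedback inhibitor of NF-κB, rose by 2.79 and 2.40, Nfkbiz by 3.32 and 1.84 and the kinase gene Pim1 by 2.62 and 1.25. Among the genes lower in both were the mismatch repair gene Msh6 at −1.81 and −0.84, Hells at −2.73 and −0.80 and the uracil glycosylase gene Ung at −2.03 and −1.05. These genes are single examples, and no group of them was tested.

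Over the 13104 genes tested in both cell types, whose comparisons share no library, 232 were higher in both, where independent lists give 53.5 (Fisher's exact p = 1.72e-92), and 79 were lower in both, where they give 21.7 (p = 2.75e-24 by the same exact test). Opposite calls were rarer than that, with 10 genes higher in LT-HSCs and lower in GMPs (34.2 for independent lists, Fisher's exact p = 7.61e-07) and 16 the other way (34.0, Fisher's exact p = 0.000546). Genes are not independent replicates, so these values of p are too small. Kit and the T cell signalling gene Ubash3a were among the first set, at 0.79 and −0.50 and at 2.73 and −0.50, and Tnfaip2, Cdc20 and Prg2 were among the second, at −2.95 and 0.92, −2.25 and 0.35, and −5.59 and 1.99. Across genes the log2 fold changes of both cell types had a Pearson r of 0.213 and a Spearman rho of 0.282.

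The libraries differed in how closely replicates resembled each other. Log2 CPM values of replicates correlated across genes by 0.983 to 0.986 in control GMPs and by 0.847 to 0.868 in AML1-ETO GMPs, and in LT-HSCs by 0.784 to 0.859 in controls and by 0.932 to 0.956 in AML1-ETO. The first 2 principal components held 43.5 and 23.0% of the variance. Xist stood at 749, 38.3, 8.67 and 172 CPM in control LT-HSCs and at 4.94, 0.300 and 3.92 CPM in AML1-ETO LT-HSCs, while Y-linked genes summed to 240, 299, 380 and 357 CPM and to 339, 351 and 324 CPM, so that several libraries held both kinds of transcript. The labels do not give the sex of the mice or say whether cells of several mice were pooled.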
